A study of Mus musculus with 10 samples.

How the data were processed

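The series measured RNA in ER-Hoxa9-Lys-GFP cells, a cultured mouse myeloid progenitor line from the C57BL/6 strain. Per the labels' protocols, the cells grew in RPMI with serum and medium conditioned with stem cell factor, and estradiol (E2) was removed with washes in buffer followed by medium lacking it. RNA was isolated with a column kit and libraries were made with a TruSeq kit. As background, Hoxa9 fused to the hormone-binding part of the estrogen receptor is active while E2 is present and holds such cells as progenitors. The 10 libraries fell into 5 groups of 2 by their titles: untreated (E2 kept), E2 withdrawn for 24, 40 or 72 h and then given back for 96, 80 or 48 h (the 24 h, 40 h and 72 h groups), and E2 withdrawn for 120 h (the 120 h group). The titles give the withdrawal times but not the add-back, whose times are those of the sample annotation used here. The titles number the libraries of each group 1 and 2. The labels do not say whether the 2 came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. The design text speaks of more withdrawal times than the 3 add-back groups analysed here.

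The deposited values were RPKM (read counts divided by transcript length and by the reads of the library) per Ensembl transcript, per the file headers and names, 1 file per library and 79535 transcripts in each. Reads were aligned with STAR to GRCm38, per the submitters' processing notes, which give no version. The counting program, the annotation release, the use of strand and the filter named in the file titles are not given in the sources used here. Transcript identifiers were matched to GENCODE M21 (GRCm38): 77720 matched (97.7%), 1815 did not, and the unmatched held 2.64 to 3.24% of summed RPKM per library. Values multiplied by transcript length were whole multiples of 1 step per library, in 99.95 to 100% of the 19671 to 21446 values tested per library within a tolerance of 0.02 reads. The step gave denominators of 173620000 to 204390000 reads, so 1 read on a 2 kb transcript was worth 0.00245 to 0.00288 RPKM. Isoforms of a gene held similar values (over 4572 coding genes, the sum over isoforms was a median of 2.64 times the largest, with a median of 3 isoforms), as when a read counts for every transcript it overlaps, so isoforms were not summed.

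Each gene was represented by 1 listed transcript chosen from the annotation alone (coding first, then APPRIS principal, CCDS and longest), giving 26227 genes, 17251 of them protein-coding. The design fixed beforehand spoke of genes, and this step was added because the files list transcripts. Values were taken as log2(RPKM + 1), so fold changes are on that scale and understate the change of low genes. The 13004 genes with RPKM of at least 1 in at least 2 libraries were tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes with a mean-variance trend), with group as the only term and all 10 libraries sharing 1 estimate of the spread (5 residual and 3.04 prior degrees of freedom). The 7 comparisons were 2-sided and genes were called at a Benjamini-Hochberg (BH) adjusted p under 0.05. Gene lists, 23 in all, were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, with BH adjustment over lists within a comparison. With an estimated correlation no list was called in any of the 7 comparisons. The sources do not state whether counting used strand, so overlapping and antisense genes, and near-identical families such as Stfa1, Stfa2, Stfa3 and Stfa2l1, Ly6c1 and Ly6c2, and Bcl2a1a, Bcl2a1b and Bcl2a1d, are uncertain as single genes. Lyz2 and Lyz1 shared 15.4% and 16.1% of their 50-base windows with the other, so some of their reads may be shared.

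The retained share of the 120 h change was computed for the genes called in the 120 h group with an absolute log2 fold change of at least 1. It is the slope through 0, across genes, of each library's difference from the untreated mean on the 120 h difference, as a percent. Unchanged groups were simulated 100 times against the same controls, with the spread of each gene pooled over all groups. The tests, samples, lists, rule for named genes and main alternatives were fixed before the data were examined. The rule named Hoxa9, Meis1, Esr1, Lyz2 and Kit in every comparison. It added the 6 highest and 6 lowest log2 fold changes among called genes with mean RPKM of at least 5 in the higher group and both libraries of 1 group beyond both of the other, leaving out predicted and clone names. Per list it took up to 4 called members with the largest change and up to 2 uncalled members with the highest RPKM. It also took list members called in opposite directions in 2 comparisons. Some genes that the rule named are not reported here.

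The pipeline was tested on simulated data with 200 changed genes among the 13004, drawn only from genes with untreated RPKM over 5. A planted log2 change of 1 was recovered for 94% of genes for the 24 h and 40 h groups, 92% for the 72 h group and 89.6% for the 120 h group, all against untreated. A planted log2 change of 0.5 was recovered for 44.8% (24 h), 49.2% (40 h), 43.2% (72 h) and 55.2% (120 h). Recovery in lower genes was not simulated. Unchanged genes made up 0.2%, 0%, 3.2% and 32.4% of the simulated calls for those 4 comparisons, since the spread of each group was simulated as measured. These shares also depend on the small number of genes planted as changed. That spread, relative to the average, was 0.595 (untreated), 0.602 (24 h), 0.622 (40 h), 1.03 (72 h) and 1.69 (120 h). Replicate libraries differed by more than counting noise in all 5 groups, with a chi-square per degree of freedom of 21.5 to 221 on the recovered reads, so none were treated as 1 library. Alternatives fixed beforehand were a pseudocount of 0.1, no filter, an RPKM minimum of 5, median-of-ratios scaling, quantile normalization, fits on only the 2 groups compared, no trend, a minimum log2 fold change of 1, a replicate block, a cross-fitted share, each library left out in turn and limma voom on the recovered reads of the 4911 tested genes whose values were whole in all libraries. Alternatives added after seeing the data were array weights per group, the fit without the 120 h group, the longest transcript, the mean over transcripts, protein-coding genes only and genes with whole reads only. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.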

Results

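RNA was sequenced from 10 libraries of ER-Hoxa9-Lys-GFP cells, mouse myeloid progenitors whose Hoxa9 is fused to an estrogen receptor domain and needs E2. The series asked when cells commit to myeloid differentiation so that E2 no longer returns them to the starting state. E2 was kept (untreated), withdrawn for 120 h, or withdrawn for 24, 40 or 72 h and then restored for 96, 80 or 48 h, so every withdrawn culture was followed for 120 h and the time with E2 restored shortened as withdrawal lengthened. Each group had 2 libraries, with denominators of 173620000 to 204390000 reads. The first principal component held 83.7% of the variance and placed the libraries from the untreated (-43.7 and -43.6) to the 120 h group (110.4 and 133), with the 72 h group between (-0.5 and 9). The second held 12.3% and set the 72 h libraries apart (45 and 47.5, against -21.3 to 3.5 in the other 8). Among coding genes outside the mitochondrial genome, the 10 most abundant took 11.4 and 10.9% of RPKM in the 120 h libraries. They took 6.49 to 7.49% in the others. Among coding genes, mitochondrially encoded ones took 2.59 and 3.06% of RPKM in the 72 h libraries and 1.41 to 2.11% in the others. Values below are mean RPKM ± SD with n = 2 libraries per group, and adjusted p-values are from limma with BH adjustment.

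**Figure D1:**
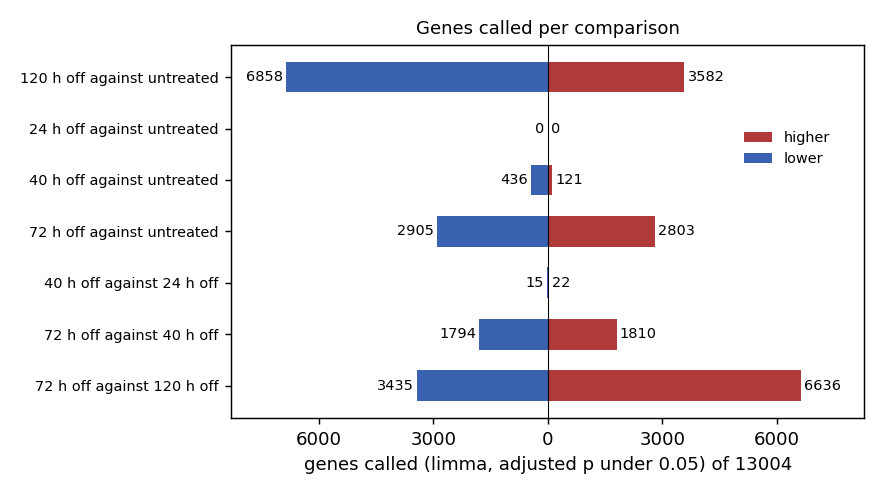
Number of genes called higher (right) and lower (left) in each of the 7 comparisons, of 13004 tested with limma at a BH adjusted p under 0.05. The 24 h group had 0 calls against untreated and the 120 h group had 3582 higher and 6858 lower.

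What continuous withdrawal did was asked by comparing the 120 h group with untreated cells. Genes of mature granulocytes and most monocyte genes rose, and 20 of 24 progenitor genes fell. With an estimated correlation no list was called. S100a8 and S100a9, the subunits of calprotectin, went from 0.533 ± 0.305 to 6039.7 ± 488 RPKM and from 0.555 ± 0.414 to 6894 ± 188 RPKM. Ltf, which encodes lactoferrin of secondary granules, went from 0.188 ± 0.0629 to 2296 ± 153 RPKM. Meis1, a homeobox partner of Hoxa9, fell from 10.9 ± 0.398 to 0.904 ± 0.281 RPKM (log2 fold change -2.65, SE 0.13, adjusted p = 4.88e-07), and Kit, the stem cell factor receptor, fell from 155 ± 4.47 to 21.1 ± 7.95 RPKM (log2 fold change -2.87, SE 0.21, adjusted p = 5.13e-06). In GRCm38 (GENCODE M21) the gene bodies lie at chromosome 11, 18879817 to 19018985 for Meis1, chromosome 5, 75574916 to 75656722 for Kit and chromosome 6, 52223100 to 52231089 for Hoxa9, and RPKM counts reads on the exons of 1 transcript of each. Of 13004 genes, 3582 were higher and 6858 lower, and 1867 and 3287 of these changed at least 2-fold.

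All 24 measured secondary granule genes rose, with a median log2 fold change of 5.74. Secondary granule genes had camera adjusted p = 9.39e-17 and adjusted p = 0.0719 with an estimated correlation. The largest rises were Chil3 (11.88), Ngp (11.36), Ltf (10.92) and Camp (9.12). All 34 tertiary granule and mature neutrophil genes rose (median 6.22), led by S100a9 (12.14), S100a8 (11.96), Stfa1 (11.62) and Stfa2l1 (10.56). Tertiary granule genes had camera adjusted p = 1.56e-19 and adjusted p = 0.0719 with an estimated correlation. Of 34 monocyte and macrophage genes 32 rose and 2 fell (median 4.52), among them Ly6c2 (8.33), Gpnmb (7.97), Cd14 (7.46) and Clec4a2 (7.16). Monocyte and macrophage genes had camera adjusted p = 1.82e-15 and adjusted p = 0.18 with an estimated correlation. The 16 primary granule genes, made early in the granulocyte series, were mixed, with 6 higher and 5 lower, or 8 and 4 with median-of-ratios scaling. Primary granule genes had camera adjusted p = 0.0888 and adjusted p = 0.633 with an estimated correlation. Fcnb (7.97), Igsf6 (6.68), Ms4a3 (5.07) and Elane (4.07) rose, while Plac8 (-0.11) and Prtn3 (0.24) were not called. Plac8 turned to a called 0.43 with quantile normalization, and Prtn3 to a called -0.38 without 120 h replicate 1 and a called 0.86 without replicate 2.

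Among progenitor and Hoxa9-Meis1 genes 20 of 24 fell and 2 rose (median -2.40). Progenitor genes had camera adjusted p = 2.76e-04 and adjusted p = 0.352 with an estimated correlation. The receptor Flt3 (-6.30), the ligand Angpt1 (-5.55), the transcription factor Sox4 (-5.02) and Adgrg1 (-5.01) fell most, and Lmo2 (0.13) and Ikzf2 (-0.20) were not called. Lmo2 was called at 0.56 with median-of-ratios scaling and 0.31 with quantile normalization, and Ikzf2 at -0.30 without 120 h replicate 2. Hoxa9 itself rose, from 55.1 ± 6.89 to 96.2 ± 2.40 RPKM (log2 fold change 0.80, SE 0.16, adjusted p = 0.00158), and Esr1 rose by 0.72. The Esr1 to Hoxa9 ratio was 0.115 to 0.121 in all 10 libraries, and reads of the fusion cannot be separated from those of the endogenous genes. Lymphoid genes fell in 11 of 12 cases and rose in 1 (median -3.04), led by Igll1 (-6.79), Rag2 (-4.93), Ebf1 (-4.62) and Thy1 (-4.35). Lymphoid genes had camera adjusted p = 0.00235 and adjusted p = 0.207 with an estimated correlation. Igll1 and Ctla2a, Aebp1, Flt3, Cnn3 and Serpinf1 were the 6 lowest genes by the naming rule, at -6.79 to -6.18.

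S phase genes fell in 31 of 32 cases (median -1.47), with Ung (-2.44), Chaf1b (-2.03), Gins1 (-2.00) and Mcm7 (-1.98), and G2 and M phase genes in 32 of 32 (median -0.99), with Ccnb1 (-1.47), Cdk1 (-1.41), Aurkb (-1.31) and Cdc20 (-1.29). S phase genes had camera adjusted p = 4.73e-04 and adjusted p = 0.617 with an estimated correlation. G2 and M phase genes had camera adjusted p = 0.00407 and adjusted p = 0.633 with an estimated correlation. With median-of-ratios scaling 26 and 18 members of these lists fell and none rose. Ribosome biogenesis and Myc target genes fell in 28 of 28 (median -2.03), with Gnl3 (-2.69), Dkc1 (-2.59), Srm (-2.54) and Odc1 (-2.51). Ribosome biogenesis genes had camera adjusted p = 2.77e-06 and adjusted p = 0.50 with an estimated correlation. Chromatin modifying enzymes had 7 higher and 20 lower of 38 (median -0.30, turning to 0.05 with 15 higher and 16 lower with median-of-ratios scaling), with Cbx2 (-2.89) and Dnmt3b (-2.26) lowest. Chromatin modifying enzymes had camera adjusted p = 0.48 and adjusted p = 0.806 with an estimated correlation.

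All 6 NADPH oxidase genes (median 2.19), all 25 interferon stimulated genes (median 3.37) and all 26 phagocyte adhesion and Fc receptor genes (median 3.06) rose, with Cybb at 8.21, Oasl2 at 5.98 and Itgam at 7.39. NADPH oxidase genes had camera adjusted p = 2.97e-05 and adjusted p = 0.0719 with an estimated correlation. Interferon stimulated genes had camera adjusted p = 7.88e-13 and adjusted p = 0.299 with an estimated correlation. The phagocyte list had camera adjusted p = 2.27e-15 and adjusted p = 0.0719 with an estimated correlation. Lysosome genes rose in 22 of 25 cases and fell in 1, led by Ctsb (3.44) and Lipa (3.13). Lysosome genes had camera adjusted p = 7.99e-11 and adjusted p = 0.0719 with an estimated correlation. Inflammatory cytokines and chemokines rose in 18 of 21 and fell in 1, led by Il1b (6.32) and Ccl2 (5.92). The cytokine list had camera adjusted p = 4.12e-09 and adjusted p = 0.207 with an estimated correlation. Myeloid transcription factors rose in 25 of 31 and fell in 4, led by Id2 (5.13), Fos (4.60), Klf6 (4.53) and Egr2 (4.11). The transcription factor list had camera adjusted p = 4.12e-09 and adjusted p = 0.0719 with an estimated correlation. Apoptosis regulators had 11 higher and 7 lower of 19, with the Bcl2a1b paralog at 4.75. Apoptosis regulators had camera adjusted p = 0.0145 and adjusted p = 0.208 with an estimated correlation. Adjusted over the list alone, counts equalled those over all genes for all lists named for this comparison except the mitochondrially encoded genes.

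Lists of other cell types moved in both directions. Mast cell, basophil and eosinophil genes had 9 higher and 4 lower of 13, with Ear2 at 6.41 and the basophil protease Mcpt8 at -4.80; the camera adjusted p was 0.142 with median-of-ratios scaling and 0.0521 with quantile normalization. The mast cell, basophil and eosinophil list had camera adjusted p = 0.0209 and adjusted p = 0.429 with an estimated correlation. Erythroid and megakaryocyte genes had 3 higher and 5 lower of 8, and dendritic cell and MHC class II genes 7 higher and 3 lower of 10. Erythroid and megakaryocyte genes had camera adjusted p = 0.862 and adjusted p = 0.874 with an estimated correlation. Dendritic cell and MHC class II genes had camera adjusted p = 0.0526 and adjusted p = 0.617 with an estimated correlation. Cholesterol synthesis genes had 1 higher and 16 lower of 22. Cholesterol synthesis genes had camera adjusted p = 0.0951 and adjusted p = 0.772 with an estimated correlation. Stress and RNA quality genes had 6 higher and 8 lower of 15, with a median of -0.49, a mean of 0.23 and camera's direction up. Stress and RNA quality genes had camera adjusted p = 0.527 and adjusted p = 0.633 with an estimated correlation. Of 11 mitochondrially encoded genes 2 rose and 3 fell, or 0 and 1 when adjusted over the list alone (median 0.19, mean -0.002). The mitochondrial list had camera adjusted p = 0.451 and adjusted p = 0.817 with an estimated correlation. With median-of-ratios scaling 6 mitochondrially encoded genes were higher and 1 lower (median 0.63), and cholesterol synthesis genes were 5 higher and 12 lower. The median log2 fold change over all genes was -0.36, and median-of-ratios scaling moved it to -0.002 and quantile normalization to -0.18. The share of calls that were higher was 34.3%, and 50.5% with median-of-ratios scaling (5125 higher, 5016 lower). The 120 h libraries varied most. In simulated data with that spread and only 200 changed genes among 13004, 32.4% of calls in this comparison were unchanged genes. That share cannot be carried over to the 10440 calls made here, since it depends on how many genes truly change.

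Whether a 24 h withdrawal left a trace after 96 h with E2 was asked next. No gene of 13004 passed limma's BH adjusted threshold. At an unadjusted p under 0.05 there were 365 genes against 650 expected by chance, and limma voom on recovered reads also called 0. The number was higher in fits that left out or down-weighted the 120 h libraries. It was 798 without the 120 h group, 800 without either of its libraries, 1406 with only the 2 groups compared and 1548 with array weights, all above 650. The progenitor genes Meis1, Kit and Hoxa9 stood at 10.4 ± 0.395, 146 ± 8.38 and 61.5 ± 2.75 RPKM against 10.9 ± 0.398, 155 ± 4.47 and 55.1 ± 6.89 in untreated cells, with log2 fold changes of -0.07, -0.09 and 0.16. The largest log2 fold change among the genes named for this comparison was that of the monocyte surface gene Ly6c2, 0.571 and 0.683 RPKM in untreated and 4.05 and 3.45 in 24 h libraries (log2 fold change 1.54, SE 0.21, adjusted p = 0.314). Prg2, an eosinophil granule gene, had a log2 fold change of 1.44.

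List tests called 7 of 23 lists at the preset correlation and 0 with an estimated correlation. The lymphoid list had a median log2 fold change of -0.23, with 0 members called over all genes. Lymphoid genes had camera adjusted p = 1.80e-08 and adjusted p = 0.188 with an estimated correlation, with 0 higher and 2 lower when adjusted over the list alone. The cholesterol synthesis list had a median of 0.13, the ribosome biogenesis and Myc target list 0.08 and the mitochondrially encoded list 0.29, each with 0 members called over all genes or over the list alone. Cholesterol synthesis genes had camera adjusted p = 1.54e-05 and adjusted p = 0.782 with an estimated correlation. Ribosome biogenesis genes had camera adjusted p = 1.20e-04 and adjusted p = 0.782 with an estimated correlation. The mitochondrial list had camera adjusted p = 1.12e-04 and adjusted p = 0.782 with an estimated correlation. The progenitor list had a median of -0.09, the primary granule list 0.01 and the monocyte and macrophage list 0.02. Progenitor genes had camera adjusted p = 0.0157 and adjusted p = 0.782 with an estimated correlation, with 0 higher and 1 lower when adjusted over the list alone. Primary granule genes had camera adjusted p = 0.00596 and adjusted p = 0.782 with an estimated correlation, with 3 higher and 0 lower when adjusted over the list alone. Monocyte and macrophage genes had camera adjusted p = 0.048 and adjusted p = 0.782 with an estimated correlation, with 2 higher and 0 lower when adjusted over the list alone. With median-of-ratios scaling and quantile normalization the monocyte and macrophage list was at adjusted p = 0.0768 and 0.159. The count of called genes was 3 without 120 h replicate 1, 3 without 120 h replicate 2 and 3 without the whole 120 h group, and these genes, chosen after their values were seen, were Ly6c2 (1.54), Crip1 (-0.67) and Sdc4 (-1.10). A fit on only the 2 groups compared gave 4, with Ms4a3 (1.05) added, array weights gave 34, a pseudocount of 0.1 gave 2 and no filter gave 3. The 34 were 11 higher and 23 lower. They included Elane (1.49), Mmp8 (1.15), Fcnb (0.87), Thy1 (-0.82), Fgf3 (-0.75) and Mycn (-0.61), which were called in the same direction in the 40 h group. These genes were picked after their values were seen, and the 34 were not compared with the 40 h group as a set.

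After 40 h without E2 and 80 h with it, Ly6c2, Elane and some other myeloid genes stood above untreated cells and 7 of 12 lymphoid genes below. With an estimated correlation no list was called, the lymphoid list included. Ly6c2 rose from 0.627 ± 0.0792 to 31.7 ± 8.34 RPKM (log2 fold change 4.31, SE 0.21, adjusted p = 2.07e-04), and Elane, neutrophil elastase, from 2.43 ± 1.06 to 41.1 ± 5.03 (log2 fold change 3.65, SE 0.42, adjusted p = 0.00471). Ms4a3 (3.39), Prg2 (3.15), Gda (2.70) and the ribosomal RNA gene n-R5-8s1 (2.54) were the other highest. Thy1, a surface protein of T cells, fell from 25.8 ± 1.21 to 5.71 ± 1.64 RPKM (log2 fold change -2.02, SE 0.21, adjusted p = 0.00346), followed by Fgf3 (-1.85), Sdc4 (-1.78), H2-Ob (-1.62), Myl4 (-1.59) and Crip1 (-1.52). In all, 121 genes were higher and 436 lower, 37 and 39 of them at least 2-fold. Meis1 (-0.37, adjusted p = 0.17), Kit (-0.17, adjusted p = 0.776) and Hoxa9 (0.37, adjusted p = 0.265) were not called, nor were Esr1 (0.32) and Lyz2 (0.01).

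Lymphoid genes fell in 7 of 12 cases (median -0.69), with Thy1 (-2.02), Dntt (-1.49), Rag1 (-1.03) and Cd79a (-0.91). Lymphoid genes had camera adjusted p = 8.96e-11 and adjusted p = 0.114 with an estimated correlation, with 0 higher and 11 lower when adjusted over the list alone. Primary granule genes rose in 4 of 16, with Elane (3.65), Ms4a3 (3.39), Igsf6 (2.18) and Fcnb (2.15), while Mpo (-0.17) and Ctsg (0.20) were not called. Primary granule genes had camera adjusted p = 0.00279 and adjusted p = 0.762 with an estimated correlation, with 4 higher and 1 lower when adjusted over the list alone. Among monocyte and macrophage genes 6 rose and 2 fell of 34, including Ly6c1 (1.84), Adgre1 (1.56) and Ms4a6c (1.20). Monocyte and macrophage genes had camera adjusted p = 0.0144 and adjusted p = 0.779 with an estimated correlation, with 7 higher and 3 lower when adjusted over the list alone. Secondary granule genes rose in 2 of 24, Mmp8 (2.53) and Hp (1.40), and Ltf was not called (0.11). Secondary granule genes had camera adjusted p = 0.0355 and adjusted p = 0.762 with an estimated correlation, with 3 higher and 0 lower when adjusted over the list alone. Tertiary granule genes had 4 higher and 2 lower of 34, among them Slpi (1.15). Tertiary granule genes had camera adjusted p = 0.0065 and adjusted p = 0.762 with an estimated correlation, with 6 higher and 2 lower when adjusted over the list alone. Progenitor genes fell in 4 of 24, Mycn (-1.30), Egfl7 (-0.97), Hlf (-0.56) and Erg (-0.51). Progenitor genes had camera adjusted p = 0.00678 and adjusted p = 0.762 with an estimated correlation, with 1 higher and 7 lower when adjusted over the list alone. Ribosome biogenesis and Myc target genes had 0 called members over all genes or over the list alone and a median of 0.31. Ribosome biogenesis genes had camera adjusted p = 2.82e-08 and adjusted p = 0.762 with an estimated correlation. S phase genes had 0 called and a median of 0.07, and G2 and M phase genes had 0 called and a median of -0.09. S phase genes had camera adjusted p = 0.20 and adjusted p = 0.885 with an estimated correlation. G2 and M phase genes had camera adjusted p = 0.392 and adjusted p = 0.91 with an estimated correlation. Mitochondrially encoded genes had 0 called and a median of 0.37. The mitochondrial list had camera adjusted p = 0.00279 and adjusted p = 0.762 with an estimated correlation. Lysosome genes, which mostly rose at 120 h, had 0 higher and 2 lower of 25 and a median of -0.21. Lysosome genes had camera adjusted p = 0.0065 and adjusted p = 0.762 with an estimated correlation, with 1 higher and 3 lower when adjusted over the list alone. The dendritic cell and MHC class II list had 0 higher and 1 lower of 10, the erythroid and megakaryocyte list 0 and 2 of 8 and the cholesterol synthesis list 1 and 0 of 22. Dendritic cell and MHC class II genes had camera adjusted p = 0.0144 and adjusted p = 0.762 with an estimated correlation, with 0 higher and 4 lower when adjusted over the list alone. Erythroid and megakaryocyte genes had camera adjusted p = 0.0379 and adjusted p = 0.762 with an estimated correlation, with 0 higher and 3 lower when adjusted over the list alone. Cholesterol synthesis genes had camera adjusted p = 7.36e-04 and adjusted p = 0.762 with an estimated correlation, with 1 higher and 0 lower when adjusted over the list alone.

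The count of 557 in this comparison moved with the libraries fitted. It was 41 without untreated replicate 1, 83 without untreated replicate 2, 305 without 24 h replicate 1, 304 without 24 h replicate 2, 62 without 40 h replicate 1, 222 without 40 h replicate 2, 1785 without 120 h replicate 1 and 1789 without 120 h replicate 2, and 1797 without the whole 120 h group, 1988 with only the 2 groups compared, 2859 with array weights, 76 with a log2 minimum of 1 and 144 with limma voom. Elane was at adjusted p = 0.0563 without untreated replicate 1 and 0.0659 without 40 h replicate 1, Thy1 at 0.0858 with a pseudocount of 0.1, and Meis1 at 0.0489 and 0.0488 without 120 h replicate 1 and 2. Without untreated replicate 1 the adjusted p was 0.0549 for Ms4a3, 0.0543 for H2-Ob and 0.0543 for Ly6c1. Over the fits that changed the scaling or pseudocount or left out libraries, Hlf lost its call in 10 (adjusted p up to 0.30), Erg in 7, Egfl7 in 5 (up to 0.199), Slpi and Ms4a6c in 4, Rag1 and Cd79a in 3, and Prg2 (up to 0.129), Fcnb and Hp in 2. With quantile normalization the secondary granule list was at adjusted p = 0.165 and the monocyte and macrophage list at 0.0626.

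The step from 24 to 40 h of withdrawal gave 22 genes higher and 15 lower in the 40 h group than in the 24 h group. Ly6c2 was higher (log2 fold change 2.76, SE 0.21, adjusted p = 0.00669), as were n-R5-8s1 (2.16), Gda (1.84), Igsf6 (1.57), Mtus1 (1.55) and Tlr4 (1.18). The lowest were Fgf3 (-1.10), Myl4 (-0.91), Asic4 (-0.91), Ctla2a (-0.87), Tnni1 (-0.86) and Crip1 (-0.85). The lymphoid list had a median of -0.44 with 0 called over all genes, and the primary granule list a median of 0.19 with 1 called. Lymphoid genes had camera adjusted p = 6.82e-11 and adjusted p = 0.111 with an estimated correlation, with 0 higher and 9 lower when adjusted over the list alone. Primary granule genes had camera adjusted p = 0.00146 and adjusted p = 0.892 with an estimated correlation, with 4 higher and 1 lower when adjusted over the list alone. Meis1 (-0.30), Kit (-0.08), Hoxa9 (0.20), Esr1 (0.19) and Lyz2 (0.06) were not called. The count of 37 was 4 without untreated replicate 1, 4 without untreated replicate 2, 0 without 24 h replicate 1, 0 without 24 h replicate 2, 4 without 40 h replicate 1, 19 without 40 h replicate 2, 12 without 72 h replicate 1, 12 without 72 h replicate 2, 233 without 120 h replicate 1 and 237 without 120 h replicate 2. It was 238 without the 120 h group, 160 with only the 2 groups compared, 493 with array weights, 75 with coding genes only, 19 with limma voom and 11 with a log2 minimum of 1, and Ly6c2 was at adjusted p = 0.113 and 0.174 without 24 h replicate 1 and 2. Every gene named for this step thus lost its call without either 24 h library.

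After 72 h without E2 and 48 h with it, granule and monocyte genes were among the highest against untreated cells, and Meis1 was lower. With an estimated correlation no list was called. Ly6c2 rose from 0.627 ± 0.0792 to 588 ± 28.5 RPKM (log2 fold change 8.50, SE 0.21, adjusted p = 1.54e-07), Elane from 2.43 ± 1.06 to 278 ± 22.8 (log2 fold change 6.38, SE 0.42, adjusted p = 1.14e-05) and Chil3, a chitinase-like protein of myeloid cells, from 0.928 ± 0.562 to 406 ± 80.2 (log2 fold change 7.74, SE 0.26, adjusted p = 4.06e-07). Ms4a3 (6.57), S100a9 (6.50) and S100a8 (6.44) were the other highest. Meis1 fell to 1.24 ± 0.0665 RPKM (log2 fold change -2.41, SE 0.13, adjusted p = 3.37e-06), and the 6 lowest were Aebp1 (-5.95), Gas6 (-5.52), Igll1 (-4.97), Mmp14 (-4.86), Nrgn (-4.69) and Ctla2a (-4.64). Kit was at 103 ± 4.46 RPKM and not called (-0.58, adjusted p = 0.056), and Lyz2 (0.05) was not called either. Kit was called without the 120 h group, at adjusted p = 8.82e-04. Of 13004 genes 2803 were higher and 2905 lower, 492 and 724 of them at least 2-fold.

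Secondary granule genes rose in 18 of 24 cases and fell in 1 (median 1.54), with Chil3 (7.74), Mmp8 (6.01), Ngp (4.53) and Ltf (4.38). Secondary granule genes had camera adjusted p = 7.63e-09 and adjusted p = 0.334 with an estimated correlation, with 19 higher and 1 lower when adjusted over the list alone. Tertiary granule and mature neutrophil genes rose in 25 of 34 and fell in 3 (median 1.82). Tertiary granule genes had camera adjusted p = 1.09e-09 and adjusted p = 0.354 with an estimated correlation, with 27 higher and 3 lower when adjusted over the list alone. Primary granule genes rose in 9 of 16 and fell in 1 (median 1.01), and Mpo (0.93) and Ctsg (0.49) were not called. Primary granule genes had camera adjusted p = 3.41e-04 and adjusted p = 0.513 with an estimated correlation, with 11 higher and 1 lower when adjusted over the list alone. Mpo and Ctsg were called without the 120 h group, at adjusted p = 5.29e-04 and 0.00682. Monocyte and macrophage genes had 19 higher and 4 lower of 34, led by Ly6c2 (8.50), Ly6c1 (5.68) and Gpnmb (4.53). Monocyte and macrophage genes had camera adjusted p = 5.02e-06 and adjusted p = 0.513 with an estimated correlation, with 19 higher and 4 lower when adjusted over the list alone. Lymphoid genes fell in 11 of 12 (median -2.49), with Igll1 (-4.97), Thy1 (-4.59), Rag2 (-3.52) and Dntt (-3.32). Lymphoid genes had camera adjusted p = 7.76e-09 and adjusted p = 0.194 with an estimated correlation, with 0 higher and 11 lower when adjusted over the list alone. Progenitor genes had 14 lower and 5 higher of 24, with Egfl7 (-3.87), Hlf (-3.20), Flt3 (-3.12) and Angpt1 (-2.83), and Myb (0.01) and Myc (0.15) were not called. Progenitor genes had camera adjusted p = 3.41e-04 and adjusted p = 0.513 with an estimated correlation, with 5 higher and 15 lower when adjusted over the list alone.

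Hoxa9 rose to 87.8 ± 20.4 RPKM (log2 fold change 0.65, SE 0.16, adjusted p = 0.0116) and Esr1 by 0.58. Without untreated replicate 1 or 72 h replicate 2, Hoxa9 was at 0.52 (adjusted p = 0.0868) and 0.41 (adjusted p = 0.0665), and Esr1 at 0.45 (adjusted p = 0.101) and 0.38 (adjusted p = 0.0853). Ribosome biogenesis and Myc target genes, all lower at 120 h, rose in 13 of 28 cases and fell in 0 (median 0.46), with Utp20 (1.10), Rrp12 (1.00) and Nat10 (0.86). Ribosome biogenesis genes had camera adjusted p = 3.03e-04 and adjusted p = 0.614 with an estimated correlation, with 16 higher and 0 lower when adjusted over the list alone. S phase genes had 1 higher and 2 lower of 32, and G2 and M phase genes 1 higher and 0 lower of 32. S phase genes had camera adjusted p = 0.91 and adjusted p = 0.98 with an estimated correlation, with 0 higher and 1 lower when adjusted over the list alone. G2 and M phase genes had camera adjusted p = 0.326 and adjusted p = 0.927 with an estimated correlation, with 0 higher and 0 lower when adjusted over the list alone. Phagocyte adhesion and Fc receptor genes had 16 higher and 6 lower of 26, interferon stimulated genes 13 and 2 of 25, NADPH oxidase genes 4 and 0 of 6 and inflammatory cytokines and chemokines 9 and 2 of 21. The phagocyte list had camera adjusted p = 0.00527 and adjusted p = 0.524 with an estimated correlation, with 17 higher and 7 lower when adjusted over the list alone. Interferon stimulated genes had camera adjusted p = 0.00626 and adjusted p = 0.651 with an estimated correlation, with 13 higher and 2 lower when adjusted over the list alone. NADPH oxidase genes had camera adjusted p = 0.012 and adjusted p = 0.334 with an estimated correlation, with 5 higher and 0 lower when adjusted over the list alone. The cytokine list had camera adjusted p = 0.0206 and adjusted p = 0.614 with an estimated correlation, with 11 higher and 2 lower when adjusted over the list alone. Myeloid transcription factors had 13 higher and 6 lower of 31, and the camera adjusted p was 0.0609 with quantile normalization. The transcription factor list had camera adjusted p = 0.0493 and adjusted p = 0.56 with an estimated correlation, with 14 higher and 6 lower when adjusted over the list alone. Of mitochondrially encoded genes 6 of 11 rose, led by mt-Nd4 (1.10) and mt-Nd4l (1.09). The mitochondrial list had camera adjusted p = 0.00626 and adjusted p = 0.614 with an estimated correlation, with 7 higher and 0 lower when adjusted over the list alone. The count of 5708 was 3604 without untreated replicate 1, 3583 without untreated replicate 2 and 3777 without 72 h replicate 2, 1216 with a log2 minimum of 1 and 1814 with limma voom.

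Between the 40 and 72 h withdrawals 1810 genes were higher and 1794 lower in the 72 h group, 353 and 378 of them at least 2-fold. Chil3 (6.77), S100a9 (5.76), S100a8 (5.74), Lyz1 (5.09), Retnlg (4.74) and Stfa1 (4.59) were highest, and Aebp1 (-4.74), Igll1 (-4.60), Gas6 (-4.39), Mmp14 (-4.25), Nrgn (-4.03) and Cd72 (-3.71) lowest. Meis1 was lower in the 72 h group (log2 fold change -2.04, SE 0.13, adjusted p = 1.62e-05), whereas Kit (-0.41), Hoxa9 (0.28), Esr1 (0.26) and Lyz2 (0.04) were not called. Kit was called without the 120 h group (adjusted p = 0.00731), and Hoxa9 at 0.52 without 72 h replicate 1 (adjusted p = 0.0404). Secondary granule genes rose in 18 of 24, tertiary granule genes in 25 of 34 with 2 lower and lysosome genes in 11 of 25. Secondary granule genes had camera adjusted p = 5.22e-11 and adjusted p = 0.198 with an estimated correlation, with 18 higher and 1 lower when adjusted over the list alone. Tertiary granule genes had camera adjusted p = 3.60e-12 and adjusted p = 0.198 with an estimated correlation, with 26 higher and 3 lower when adjusted over the list alone. Lysosome genes had camera adjusted p = 2.74e-04 and adjusted p = 0.224 with an estimated correlation, with 13 higher and 1 lower when adjusted over the list alone. Lymphoid genes fell in 11 of 12. Lymphoid genes had camera adjusted p = 2.55e-09 and adjusted p = 0.173 with an estimated correlation, with 1 higher and 11 lower when adjusted over the list alone. Stress and RNA quality genes had 1 higher and 5 lower of 15 (median -0.30). Stress and RNA quality genes had camera adjusted p = 0.0132 and adjusted p = 0.198 with an estimated correlation, with 1 higher and 6 lower when adjusted over the list alone. Against untreated cells, 2 of that list were higher and 6 lower in the 72 h group (median -0.34). Stress and RNA quality genes had camera adjusted p = 0.0726 and adjusted p = 0.366 with an estimated correlation, with 2 higher and 8 lower when adjusted over the list alone. The count of 3604 was 1977 without 40 h replicate 1, 2073 without 40 h replicate 2, 2025 without 72 h replicate 2, 6075 without 120 h replicate 1 and 6082 without 120 h replicate 2. It was 6082 without the whole 120 h group, 731 with a log2 minimum of 1 and 1132 with limma voom.

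**Figure D2:**
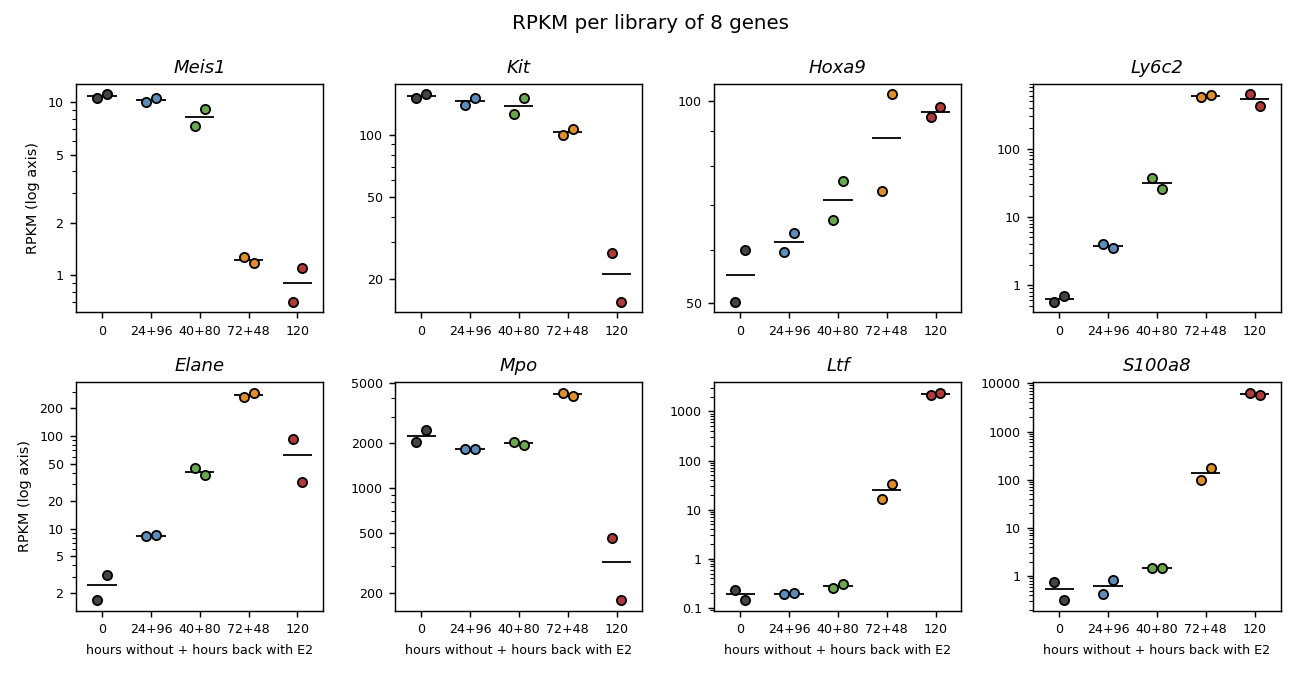
RPKM (log axes) of 8 genes in each of the 10 libraries, by hours without E2 and hours with E2 restored; points are libraries and lines are group means (n = 2). Meis1 is at 10.6 and 11.2 RPKM in untreated libraries and 1.28 and 1.19 in 72 h libraries, and Ly6c2 at 0.571 and 0.683 in untreated libraries and 568 and 608 in 72 h libraries.

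What the add-back at 72 h did was seen by comparing the 72 h with the 120 h group, cultures followed for the same total time. Mature granulocyte genes were lower and 17 of 24 progenitor genes and most proliferation genes higher in the 72 h group. With an estimated correlation no list was called, and fewer G2 and M phase genes were higher with median-of-ratios scaling (13 of 32). Mpo, myeloperoxidase of primary granules, was at 4236 ± 139.5 RPKM against 320.4 ± 202 (log2 fold change 3.88, SE 0.38, adjusted p = 3.36e-05), and Kit at 103 ± 4.46 against 21.1 ± 7.95 (log2 fold change 2.29, SE 0.21, adjusted p = 2.44e-05). Camp, the cathelicidin precursor, was at 4.23 ± 1.35 against 588 ± 113 (log2 fold change -6.83, SE 0.18, adjusted p = 1.80e-07). Cnn3 (4.68), Ctsg (3.95), Chchd10 (3.77), Muc13 (3.72) and Samd4 (3.65) were also among the highest, and Ngp (-6.82), Stfa3 (-6.75), Stfa2l1 (-6.55), Ltf (-6.53) and Stfa2 (-6.27) among the lowest. Meis1 (0.24, adjusted p = 0.12) and Hoxa9 (-0.15, adjusted p = 0.408) were not called. Meis1 was at adjusted p = 0.0199 without 120 h replicate 2, Hoxa9 at -0.39 with adjusted p = 0.0404 without 72 h replicate 2 and at -0.59 with adjusted p = 0.00719 with median-of-ratios scaling, and Esr1 (-0.14, not called) at -0.55 with adjusted p = 0.00701 with that scaling. Lyz2 had a log2 fold change of -1.75 in the 72 h group.

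All 24 secondary granule genes, all 34 tertiary granule genes and all 25 interferon stimulated genes were lower, as were all 21 cytokines and chemokines. Secondary granule genes had camera adjusted p = 3.41e-16 and adjusted p = 0.0779 with an estimated correlation, with 0 higher and 24 lower when adjusted over the list alone. Tertiary granule genes had camera adjusted p = 1.03e-18 and adjusted p = 0.0779 with an estimated correlation, with 0 higher and 34 lower when adjusted over the list alone. Interferon stimulated genes had camera adjusted p = 5.58e-13 and adjusted p = 0.293 with an estimated correlation, with 0 higher and 25 lower when adjusted over the list alone. The cytokine list had camera adjusted p = 4.57e-11 and adjusted p = 0.168 with an estimated correlation, with 0 higher and 21 lower when adjusted over the list alone. S phase genes were higher in 32 of 32, G2 and M phase genes in 28 of 32 and ribosome biogenesis and Myc target genes in 28 of 28. S phase genes had camera adjusted p = 9.07e-05 and adjusted p = 0.549 with an estimated correlation, with 32 higher and 0 lower when adjusted over the list alone. G2 and M phase genes had camera adjusted p = 0.00717 and adjusted p = 0.692 with an estimated correlation, with 29 higher and 0 lower when adjusted over the list alone. Ribosome biogenesis genes had camera adjusted p = 2.58e-08 and adjusted p = 0.419 with an estimated correlation, with 28 higher and 0 lower when adjusted over the list alone. With median-of-ratios scaling 27 S phase and 13 G2 and M phase genes were higher. Progenitor genes were higher in 17 of 24, with Flt3 (3.18), Cd34 (2.99), Myb (2.81) and Angpt1 (2.72). Progenitor genes had camera adjusted p = 0.00653 and adjusted p = 0.457 with an estimated correlation, with 17 higher and 2 lower when adjusted over the list alone. Chromatin modifying enzymes had 18 higher and 6 lower, and 14 and 14 with median-of-ratios scaling. Chromatin modifying enzymes had camera adjusted p = 0.437 and adjusted p = 0.782 with an estimated correlation, with 18 higher and 6 lower when adjusted over the list alone. In all, 6636 genes were higher and 3435 lower, 2587 and 1689 at least 2-fold. Median-of-ratios scaling gave 4352 higher and 4997 lower, a share of higher calls of 46.6% against 65.9%. The count of 10071 was 8362 with only the 2 groups compared and 8266 with array weights. The 72 h and 120 h groups varied most, so the spread shared with the other groups may make these p-values too small. False calls were not simulated for this comparison. Relative to both groups, 1283 genes were above and 884 below both the untreated and the 120 h group (868 and 1189 with median-of-ratios scaling), 1009 rose against untreated but were below the 120 h group (1340 with that scaling), 1300 fell but were above it (802 with that scaling), and 5595 differed from the 120 h group but were not called against untreated. The 1283 genes above both were 629 without untreated replicate 1, 663 without untreated replicate 2, 644 without 72 h replicate 2 and 1963 without 120 h replicate 2, and 68 above and 122 below with a log2 minimum of 1.

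**Figure D3:**
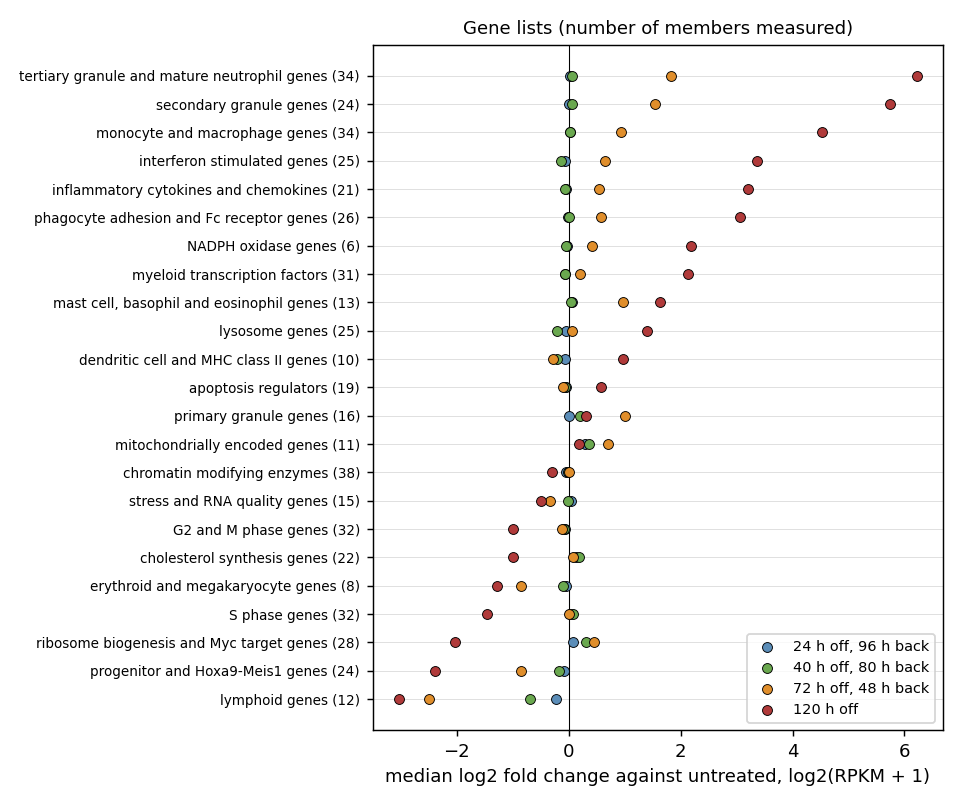
Median log2 fold change against untreated, on the log2(RPKM + 1) scale, of the 23 gene lists in the 24, 40, 72 and 120 h groups, with the number of members measured beside each list. The tertiary granule and mature neutrophil list (34 members) is at 6.22 at 120 h and 1.82 at 72 h, the lymphoid list (12 members) at -3.04 and -2.49; with median-of-ratios scaling the chromatin list turns from -0.30 to 0.05 at 120 h.

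How much of the 120 h change was present after add-back was measured over the 5154 genes called at 120 h with at least a 2-fold change. Libraries from the end of each withdrawal were not analysed here, so a change that E2 reversed cannot be told from one not yet reached, and the retained share is the share present at the end. The retained share was 1.03 ± 0.12% (SD, n = 2) in the 24 h, 4.20 ± 0.14% in the 40 h and 32.5 ± 3.97% in the 72 h group, against 0 ± 0.08% in untreated and 100 ± 8.64% in 120 h libraries. Unchanged groups simulated against the same controls gave 0.53 ± 0.12%, with a pooled spread wider than that of the untreated, 24 h and 40 h libraries. The share over the genes higher at 120 h was 0.29 ± 0.18%, 3.05 ± 0.29% and 31.7 ± 5.51% in the 24, 40 and 72 h groups, and over the lower ones 2.11 ± 0.57%, 5.89 ± 0.08% and 33.6 ± 1.71%. Per gene the median share was -0.02, 0.65 and 20.1%. Of the 5154 genes, 0, 344 (6.7%) and 2287 (44.4%) were called the same way in the 24, 40 and 72 h groups and 0, 41 and 318 the opposite way. In the 72 h group 943 of 1867 genes higher at 120 h (50.5%) and 1344 of 3287 lower (40.9%) were called the same way, among them Ly6c2, Elane and Chil3 (higher) and Meis1, Flt3 and Thy1 (lower). The 24 h share was 1.61 with a pseudocount of 0.1 and 3.42 with limma voom, the 40 h share 7.62 with limma voom, and the 344 genes were 39 without untreated replicate 1, 76 without untreated replicate 2, 221 without 24 h replicate 1, 220 without 24 h replicate 2, 55 without 40 h replicate 1, 178 without 40 h replicate 2, 663 without 120 h replicate 1 and 667 without 120 h replicate 2, 888 with array weights and 94 with limma voom.

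The add-back groups shared their controls with the 120 h group. The correlation across genes of their log2 fold changes with the 120 h change was 0.089, 0.209 and 0.622 for the 24, 40 and 72 h groups, against 0.051 in simulated unchanged groups (genes are not independent replicates). The covariance was 0.0157, 0.0773 and 0.6527 against a simulated 0.0111, differences of 0.0046, 0.0662 and 0.6416. Of the genes called in both, 94 were higher and 326 lower in the 40 h and the 120 h group (33.3 and 229.9 for independent lists), and 1538 and 2152 in the 72 h and the 120 h group (772.1 and 1532). Others were called in opposite directions. In the 40 h group 18 were higher but lower at 120 h and 78 the reverse, and in the 72 h group 694 and 423. Splitting the 2 control libraries leaves 1 for each comparison, and the correlation and the overlaps were not computed that way, so part of their excess may come from the shared controls. Over the genes called at 120 h, the share with the same sign as at 120 h was 48.7, 50.9 and 67.1%, against a simulated 51.9%. The simulation used a spread pooled over groups. That of the untreated, 24 h and 40 h libraries was 0.595, 0.602 and 0.622 of the average, so the simulated values may be too high. Only the 72 h group was above the simulated share, which cannot decide the matter for the 24 h and 40 h groups. For the retained share, taking the 120 h change from libraries of 1 replicate number and scoring those of the other gave 0.92, 4.06 and 32.84%.

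**Figure D4:**
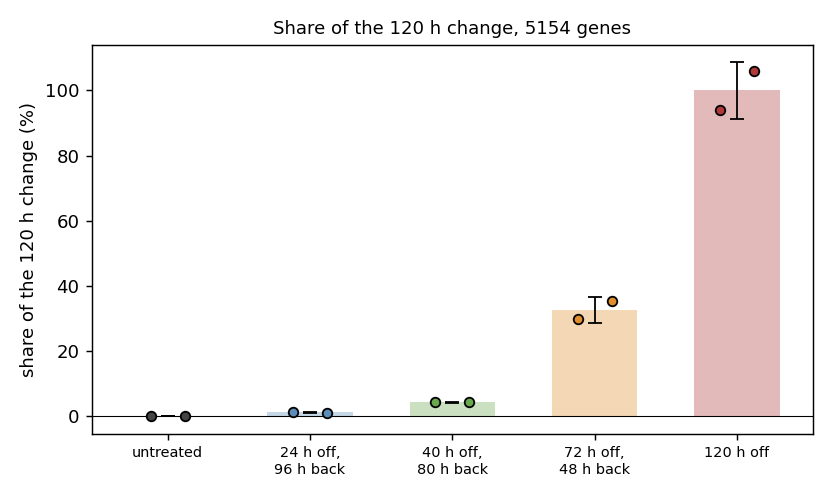
Share of the 120 h change (percent, slope over 5154 genes) in each library (points) with the group mean (bar) and SD (n = 2). The 24, 40 and 72 h groups are at 1.03, 4.20 and 32.5%, and untreated and 120 h libraries at 0 and 100% by construction of the scale.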

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

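The test for a mixture of cells was chosen only after the result was seen. Of 491 list members measured, 47 were called against untreated in opposite directions in the 72 h and 120 h groups. Entry also required a limma call between those groups, so that call is no further evidence. Over all 13004 genes, without that requirement, 694 were higher in the 72 h group and lower at 120 h, and 423 the reverse. The share of list members is thus near that over all genes. The 20 that were higher than untreated in the 72 h group and lower in the 120 h group were led by ribosome biogenesis and Myc target genes, whose differences (72 h minus 120 h, log2) were Bop1 (1.70), Ddx21 (2.23), Nat10 (2.66), Ncl (2.24), Nolc1 (2.98), Nop2 (2.17), Odc1 (3.19), Polr1a (1.46), Polr1b (2.84), Rrp12 (2.29), Rrs1 (2.09), Utp20 (2.14) and Wdr43 (2.34); over all 28 members the median difference was 2.31. Others of the 20 included Cdc45 (1.19), Cenpe (0.89), Gfi1 (1.99), Hsph1 (2.11), Insig1 (1.47) and Lin28b (1.64). The 27 that were lower than untreated in the 72 h group and higher in the 120 h group included Bst2 (-1.17), Clec4e (-1.39), Coro1a (-1.94), Ctsl (-3.22), Ddx58 (-3.20), Emilin2 (-1.76), Fcer1g (-2.10), H2-DMa (-2.58), Hmox1 (-3.04), Ier3 (-1.99), Itgal (-1.69), Kdm6b (-1.62), Mxd1 (-2.46), Npc2 (-1.31), Plek (-1.67), Relb (-2.83), Selplg (-1.06), Siglecf (-1.57), Slc2a3 (-3.71), Stat3 (-1.08), Tcn2 (-1.43), Tgfbi (-2.91), Trp53inp1 (-2.98) and Tyrobp (-2.56). With median-of-ratios scaling Cdc45 (-0.17) and Cenpe (-0.05) were no longer called at 120 h, and Tyrobp (-0.28) and Stat3 (-0.29) no longer at 72 h. Many of the 72 h calls against untreated also depended on the fit. Over the fits that changed the scaling or pseudocount or left out libraries, Stat3 and Tyrobp lost that call in 10. Odc1 lost it in 9, Ncl in 8, Ddx58 in 7 and Insig1 in 5, and the others of the 47 in 4 or fewer, some in none. Among list members outside the 47, Ccl3, Cd52 and Irf8 were lower than untreated in the 40 h group while higher in the 120 h group. Their differences of -4.23, -4.78 and -1.23 were not tested. Their 40 h calls were lost without either untreated or either 40 h library. Members of the 47 were left out of this search. Some of them, such as Ctsl, H2-DMa, Hmox1, Slc2a3 and Selplg, were also called against untreated in the 40 h group. Each of those calls was lost in 4 to 9 of the fits described above.

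More widely, 1283 genes of the 72 h group were called above and 884 below both the untreated and the 120 h group. A mixture of cells like the untreated ones and cells like the 120 h ones would place each gene between those groups, whatever the shares. Of the genes called against untreated, 38.0% were called beyond the 120 h group too, and 15.6% when a 2-fold change was also required, which argues against such a mixture as the whole cause. Scaling by total reads could matter if a few genes take many reads in the 120 h group, though shares of reads per gene were not computed. It was argued against by the 78.9% of genes beyond both that were still beyond both, on the same side, with median-of-ratios scaling. That scaling raises the 120 h values, so the genes above both were the ones it could end, and 847 of those 1283 were still above. A cell state unlike both others may account for the pattern, as a hypothesis from the same data that was not tested. It need not be particular to the 72 h group, since some of its genes leaned the same way in the 40 h group. Whether it came from the withdrawal or from the shorter time with E2 stays open because the 2 changed together and cells taken at 72 h were not analysed here.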

How the results depend on the processing

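Alternatives chosen only after the results were seen were array weights, the fit without the 120 h group, protein-coding genes only, genes with whole reads only, the longest transcript and the mean over transcripts. Over all alternatives, named genes kept their direction and side of the threshold in 18693 gene settings, were weaker in 675, stronger in 317 and reversed in 11, and list tests were the same in 1132, weaker in 115 and stronger in 41. The values for each comparison or share that moved follow by setting, with the reported values being 10440 (120 h vs untreated), 0 (24 h vs untreated), 557 (40 h vs untreated), 5708 (72 h vs untreated), 37 (40 h vs 24 h), 3604 (72 h vs 40 h), 10071 (72 h vs 120 h), 1.03 (share 24 h), 4.2 (share 40 h), 32.48 (share 72 h), 0 (same way 24 h), 344 (same way 40 h), 2287 (same way 72 h), 1283 (above both), 884 (below both), 16 (lists 120 h vs untreated), 7 (lists 24 h vs untreated), 12 (lists 40 h vs untreated), 13 (lists 72 h vs untreated), 9 (lists 40 h vs 24 h), 13 (lists 72 h vs 40 h) and 16 (lists 72 h vs 120 h). A log2 minimum of 1 gave 5154 (120 h vs untreated), 76 (40 h vs untreated), 1216 (72 h vs untreated), 11 (40 h vs 24 h), 731 (72 h vs 40 h), 4276 (72 h vs 120 h), 68 (above both) and 122 (below both). Limma voom on recovered reads, over 4911 genes instead of 13004, gave 3900 (120 h vs untreated), 144 (40 h vs untreated), 1814 (72 h vs untreated), 19 (40 h vs 24 h), 1132 (72 h vs 40 h), 3772 (72 h vs 120 h), 3.42 (share 24 h), 7.62 (share 40 h), 43.89 (share 72 h), 94 (same way 40 h), 1033 (same way 72 h), 273 (above both) and 293 (below both), and limma on the same genes gave 3927 (120 h vs untreated), 125 (40 h vs untreated), 1794 (72 h vs untreated), 11 (40 h vs 24 h), 1073 (72 h vs 40 h), 3742 (72 h vs 120 h), 79 (same way 40 h), 851 (same way 72 h), 288 (above both) and 293 (below both), so most of the fall in counts came from fewer genes tested. A fit on only the 2 groups compared gave 4 (24 h vs untreated), 1988 (40 h vs untreated) and 160 (40 h vs 24 h), array weights gave 34 (24 h vs untreated), 2859 (40 h vs untreated), 493 (40 h vs 24 h), 26 (same way 24 h) and 888 (same way 40 h), and leaving out the 120 h group gave 3 (24 h vs untreated), 1797 (40 h vs untreated), 238 (40 h vs 24 h) and 6082 (72 h vs 40 h). A pseudocount of 0.1 gave 2 (24 h vs untreated), 1.61 (share 24 h), 5.36 (share 40 h), 37.82 (share 72 h) and 1 (same way 24 h), no filter 3 (24 h vs untreated) and 4 (lists 24 h vs untreated), an RPKM minimum of 5 gave 0.84 (share 24 h) and 3.84 (share 40 h), median-of-ratios scaling 0.71 (share 24 h) and 3.79 (share 40 h) and coding genes only 75 (40 h vs 24 h). With an estimated correlation all 7 list counts were 0 (0 (lists 120 h vs untreated), 0 (lists 24 h vs untreated), 0 (lists 40 h vs untreated), 0 (lists 72 h vs untreated), 0 (lists 40 h vs 24 h), 0 (lists 72 h vs 40 h) and 0 (lists 72 h vs 120 h)). Leaving out each library in turn gave 9532 to 10909 (120 h vs untreated), 0 to 3 (24 h vs untreated), 41 to 1789 (40 h vs untreated), 3583 to 7877 (72 h vs untreated), 0 to 237 (40 h vs 24 h), 1977 to 6082 (72 h vs 40 h), 9136 to 10490 (72 h vs 120 h), 0.75 to 1.37 (share 24 h), 3.31 to 5.28 (share 40 h), 28.64 to 36.34 (share 72 h), 0 to 3 (same way 24 h), 39 to 667 (same way 40 h), 1722 to 3180 (same way 72 h), 629 to 1963 (above both), 615 to 1098 (below both); a lone library was assumed to vary like the other groups. Reversed genes were, at 120 h, Plac8 (0.428 with quantile normalization), Prtn3 (-0.38 without 120 h replicate 1) and, with median-of-ratios scaling, Nfe2 (0.337), Rnf2 (0.264), Fdft1 (0.348) and Ccl9 (0.353), and in the 72 h against the 120 h group, with that scaling, Ehmt2 (-0.367), Gusb (-0.413), Sc5d (-0.328), Bax (-0.293) and Dnajb1 (-0.32). Prtn3 kept its direction and was called, at 0.86, without 120 h replicate 2. Apart from the smaller set of genes, the cause was not tested. With the replicate number as a block the counts were 10787 (120 h vs untreated), 0 (24 h vs untreated), 693 (40 h vs untreated), 6441 (72 h vs untreated), 43 (40 h vs 24 h), 4437 (72 h vs 40 h) and 10424 (72 h vs 120 h). Under that block 796 named gene results were the same, 13 stronger and 1 weaker. Of the list tests 155 were the same, 1 stronger and 5 weaker. The labels give no shared culture or day behind a number. The correlations of replicate differences between groups were 0.03 to 0.64, all positive, with 8 of 10 over 0.1 and those among the 4 withdrawn groups at 0.21 or more, a hint from the data that libraries of 1 number share something. Depth was 173620000 to 204390000 reads per library; the chi-square per degree of freedom between replicates was 21.5 to 221.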

Other observations

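Tests of a joined transgene, of a reporter allele and of the scaling of Hoxa9 were chosen only after the results were seen, as were the genes named for iron and MHC class I. Some abundant genes of the 72 h group lay beyond both other states. The transferrin receptor Tfrc was at 35.7 ± 2.80 RPKM in untreated, 55.8 ± 3.97 in 40 h, 149 ± 2.28 in 72 h and 26.1 ± 7.10 in 120 h libraries (log2 fold change 2.03, SE 0.17, adjusted p = 4.51e-05 against untreated in limma with BH adjustment). The ferritin heavy chain Fth1 moved the other way, at 1442 ± 2.46, 1044 ± 11.7, 460.4 ± 31.6 and 1536 ± 59.1 RPKM (log2 fold change -1.65, SE 0.15, adjusted p = 5.88e-05). The MHC class I light chain B2m was at 1435 ± 26.8, 1066 ± 11.5, 493 ± 11.6 and 1521 ± 129 RPKM (log2 fold change -1.54, SE 0.15, adjusted p = 1.04e-04), and H2-D1, a class I heavy chain, at 633 ± 9.80, 432 ± 10.1, 201 and 197 in the 72 h libraries and 529 ± 96.0 (log2 fold change -1.66, SE 0.14, adjusted p = 4.41e-05). The glucose transporter Slc2a3 was at 22.2 ± 0.247 in untreated, 3.18 ± 0.506 in 72 h and 53.6 ± 6.24 RPKM in 120 h libraries (log2 fold change -2.48, SE 0.13, adjusted p = 3.82e-06), and the receptor Met at 3.25 ± 0.106, 6.24 ± 0.409, 16.6 ± 0.921 and 3.11 ± 0.652 (log2 fold change 2.05, SE 0.11, adjusted p = 4.39e-06). In the 40 h group the means of Tfrc, Fth1, B2m, H2-D1 and Met also lay outside those of the untreated and 120 h groups, on the same side. Of these only Met was called there against untreated in the main limma fit (log2 fold change 0.77, SE 0.11, adjusted p = 0.0113). That fit shares 1 spread with the more variable 120 h libraries. The others may therefore differ from untreated in the 40 h group without a call. Slc2a3 was called there against untreated too, and lost that call in 4 of the fits that changed the scaling or pseudocount or left out libraries. Values with ± are mean ± SD, n = 2, and the others are single libraries.

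Lyz1 reached 878 ± 189 RPKM at 120 h while Lyz2, listed beside it as a lysozyme gene, was at 3.49 ± 1.14 RPKM, 0.4% of Lyz1, against 0.266 ± 0.0460 in untreated cells. Only 15.4% of the 50-base windows of the Lyz2 transcript occur in a Lyz1 transcript, so reads shared between the genes are argued against as the cause. The titles name the cells ER-Hoxa9-Lys-GFP, a name that holds a reporter but not its place in the genome. A candidate explanation is that this reporter stands in place of Lyz2. Whether it does cannot be told apart from a lack of Lyz2 expression. The sequence of a reporter is outside the transcripts listed and was not analysed here.

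Hoxa9 and Esr1 were higher together in the 72 h and 120 h groups. The SD over 10 libraries of their log2 ratio was 0.0242, 7.0% of the SD of log2 Hoxa9 (0.3457), which is consistent with reads from 1 transgene that joins parts of both genes. Short noncoding Esr1 transcripts lying only in the 3' part of the gene were at 28.3 to 65.8 RPKM. The coding transcripts, which start before that part and run into it, were lower, at 4.166 to 27.953. The 4 transcripts that end before that part were at 0.098 to 3.65. Scaling by total reads was argued against, since the median-of-ratios factors (log2) differed from the untreated ones by -0.44 in the 120 h group, which lowers its genes rather than raising them, and by 0 in the 72 h group (SD within groups 0.02). Why the shared level rose after withdrawal was not tested.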
